A study of Mus musculus with 67 samples.

How the data were processed

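Liver RNA of C57BL/6 mice was measured by mRNA sequencing in 67 libraries. The mice were 24 weeks old and had eaten a high-fat diet for 12 weeks, either ad libitum or only within a daily window (time-restricted feeding). The hours of that window were not given in the sources used here. The genotypes were wild type (WT), a liver knockout of the clock activator gene Bmal1 (symbol Arntl; Bmal1LKO), a knockout of both clock repressor genes Cry1 and Cry2 (CryDKO), and a liver knockout of Rev-erb alpha and beta (symbols Nr1d1 and Nr1d2; ReverbLDKO). WT had 12 ad libitum and 11 restricted libraries, with 2 libraries per time at ZT4, 8, 12, 16, 20 and 24 except that the restricted group had 1 at ZT12. Bmal1LKO had 6 libraries per feeding, 1 at each of those times. CryDKO and ReverbLDKO had 8 per feeding, 1 every 3 hours from ZT3 to ZT24. The labels do not say whether libraries came from separate animals, so p-values measure only the spread between these libraries.

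Per the labels' protocols, RNA was isolated with the RNeasy Mini kit and 1 ug was made into libraries with a TruSeq stranded mRNA kit. The authors deposited FPKM values for 45808 gene rows in 1 table, and their processing notes name STAR, featureCounts, DESeq2 and the GRCm38 build, with no versions. The strand setting of the counting was not given in the sources used here, so reads of a gene and of a gene on the opposite strand over the same bases cannot be told apart. The FPKM of a library summed to 386198 to 1097495, so the deposited values were not scaled to a common sum. Of the gene rows, 27 had symbols turned into dates and 4 repeated another symbol. By symbol, 41893 matched a single gene of the GRCm38 annotation (GENCODE), from which identifiers, exon lengths and GC content were taken. Genes with near-identical copies (the Mup, Ugt2b, Cyp2a, Cyp2b, Serpina1, Saa and Hba families among those named) are uncertain, since the counting could divide their reads.

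FPKM values are not counts, and a count test was not used for the results given first. Low values fell on whole multiples of what 1 read was worth for the gene's length. With a tolerance of 0.1 reads, 84 to 88% of low values (up to 20 reads) of a library came out whole, which put the libraries at 9.14 to 36.09 M reads. Values of 14903 genes were whole in at least 9 of 10 libraries. Limma voom, chosen after seeing the data, tested recovered reads of 9581 genes, not picked by this rule.

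Values were analysed as log2(FPKM + 1), so a fold change is on that scale and understates the change of low genes. Genes with a mean of at least 1 FPKM over all libraries were tested, 9958 in all. One limma fit of all 67 libraries gave each group a level over 24 h and a cosine and sine of zeitgeber time with a period of 24 h, so that groups with 1 library per time shared an estimate of the spread. From this fit came the feeding effect (restricted minus ad libitum level) per genotype and as the mean of 4 genotypes, a test of whether it differed between genotypes, and the genotype effect (mutant minus WT level, mean of both feedings). Tests of the cosine and sine together gave the rhythm of each group and its differences. Genes passed at an adjusted p under 0.05. The design, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

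The 23 gene lists were core clock, fatty acid synthesis, cholesterol synthesis, bile acid and sterol export, fatty acid oxidation, glucose and glycogen, lipid droplet, acute phase, xenobiotic metabolism, Nrf2 oxidative stress, ER stress and amino acid response, heat shock, male-biased liver, female-biased liver, immune cell, stellate cell, endothelial, bile duct, adipocyte, pancreas, erythroid, cell cycle and hepatocyte genes. List directions were tested with limma camera at a preset correlation of 0.01 and one estimated per list, adjusted over the 23 lists per contrast. Camera sets a list against other genes, so its direction can differ from the median's sign. Limma fry leaves them out, so a shift of all genes can pass it.

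Named genes were chosen by rule. Arntl, Cry1, Cry2, Nr1d1, Nr1d2 and the core clock list were always eligible. For each feeding or genotype contrast, the 6 genes that rose most and the 6 that fell most with a mean of at least 5 FPKM were eligible, with up to 4 members of each list that passed and had the greatest log2 difference. The 6 genes with the smallest p were taken for each rhythm test, and 8 for the difference of feeding effects between genotypes. Predicted or unnamed genes were counted but not named, and list members that did not pass could be named with their values. A few genes that the rule selects are not reported here.

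Alternatives were another pseudocount, no filter on low values, median-of-ratios scaling, scaling to the same sum of FPKM, library weights, fits of only the groups compared, time points as categories, no time terms, 1 WT replicate number at a time, a replicate block for WT, and each library left out in turn. Chosen after seeing the data were a correction for GC content and length, the voom test, leaving out 3 doubted libraries, leaving out 8 libraries with pancreas reads, and genotype effects under restricted feeding alone. The correction regressed each library's deviation from the gene means on splines (df 5) of transcript GC content and exon length, known for 96.2% of tested genes. The doubted libraries were ad libitum WT ZT16 replicate 2, restricted WT ZT24 replicate 1 and restricted CryDKO ZT3.

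Of 263 pairs of libraries within groups, none was alike within sampling noise: the lowest chi-square per degree of freedom was 10.5 over genes with a mean of at least 50 recovered reads, and at most 0.41% of values were identical. The scripts were tested on simulated data with 200 changed genes, 50 of each size, among 9958. For the WT feeding contrast 74% of genes changed by 0.5 on the log2 scale and 98% of those changed by 1 were recovered. For CryDKO these shares were 52 and 92%, and for the difference in rhythm between feedings in CryDKO 32 and 72%. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.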

Results

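Liver transcriptomes of mice on a high-fat diet were sampled over the day in 4 genotypes, with food available at all times or only within a daily window. Recovered depth of the 67 libraries ran from 9.14 to 36.1 M reads, with group medians of 12.82 to 20.2 M. Values are log2 differences ± SE on the log2(FPKM + 1) scale unless given as FPKM, with 12 against 11 libraries for feeding in WT, 6 against 6 in Bmal1LKO and 8 against 8 in each of the other mutants. Adjusted p-values are from limma with Benjamini-Hochberg adjustment.

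The deleted genes were examined first. Arntl, which encodes the clock activator BMAL1, was at 2.00 to 7.09 FPKM with a median of 3.18 in Bmal1LKO and at 0.42 to 12.6 with a median of 7.29 in WT. It fell by 0.37 ± 0.14 on the log2 scale against WT (adjusted p = 0.0365), and with only these groups in the fit the call was lost (adjusted p = 0.152). Cry1 was at 6.65 to 14.3 FPKM in libraries labelled CryDKO, against 1.66 to 23.0 in WT, and was 0.29 ± 0.08 higher (adjusted p = 0.00201). Cry2 was at 1.94 to 3.56 FPKM in CryDKO and 1.23 to 8.01 in WT, a difference of -0.22 ± 0.10 (adjusted p = 0.0645). Nr1d1, which encodes the repressor REV-ERB alpha, was at 4.82 to 71.8 FPKM in libraries labelled ReverbLDKO and 0.12 to 33.3 in WT, and was 2.72 ± 0.14 higher (adjusted p = 1.45e-20). Nr1d2 was at 7.76 to 28.7 and 1.70 to 39.1 FPKM, and was 0.67 ± 0.15 higher (adjusted p = 0.000238). These sums run over all exons of a gene and the deleted exons are not named in the labels, so they do not check the deletions. Directions against WT below are those of libraries labelled CryDKO and ReverbLDKO.

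Library properties differed between groups. The slope of expression against GC content, in log2 per 10 percentage points, had a median of 0.391 in ad libitum WT and -0.653 in restricted WT, and medians from -0.02 to 0.148 in the mutant groups. In ReverbLDKO it was 0.148 ad libitum and -0.02 restricted, a shift in the same direction as in WT. Mitochondrial transcripts took a median of 5.16% of FPKM in ad libitum WT and 10.2% in restricted WT. Over 91 genes lying opposite a stronger gene, summed FPKM had medians of 7.89 in ad libitum WT and 27.0 in restricted WT, and of 28.0 in ad libitum ReverbLDKO and 6.73 in restricted ReverbLDKO. Bmal1LKO had 24.2 and 19.6, and CryDKO 33.6 and 25.4. mt-Nd6, encoded on the other mitochondrial strand, followed the order of these sums in WT, at medians of 0.88 and 8.8% of mt-Nd5, and in ReverbLDKO, at 11.4 and 1.12%, but not in Bmal1LKO, at 9.71 and 10.6%, or CryDKO, at 5.8 and 5.86%.

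**Figure D1:**
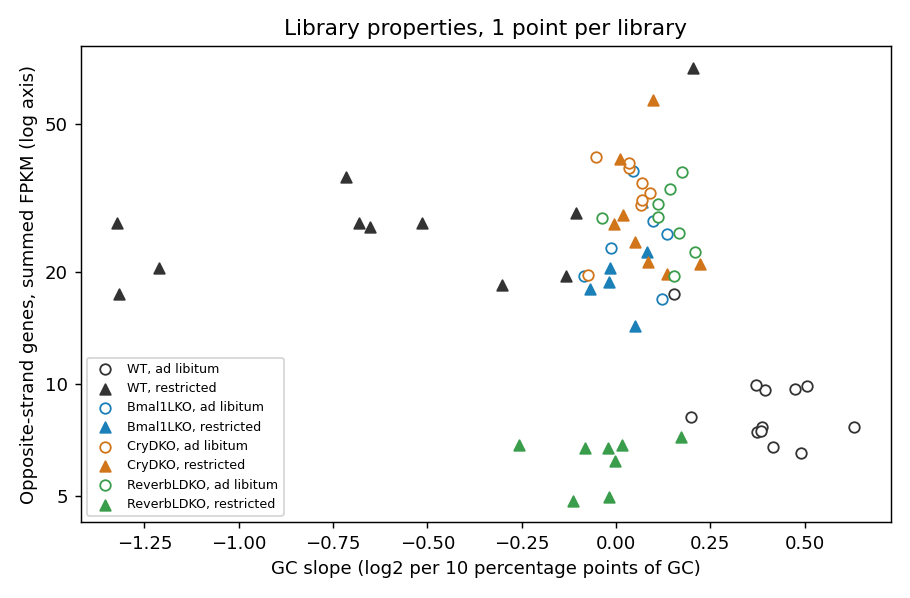
GC slope (log2 per 10 percentage points of GC, horizontal) against summed FPKM of 91 genes opposite a stronger gene (vertical, log axis), 1 point per library, by genotype and feeding. Ad libitum WT libraries run from 6.52 to 17.4 FPKM and restricted WT libraries from 17.4 to 70.8, while in ReverbLDKO the order of the feedings is the other way.

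Fasn, Srebf1 and other lipid synthesis genes were lower under restricted feeding in WT. The fatty acid and cholesterol synthesis lists passed fry (adjusted p = 0.000235 and 0.0144). They did not pass camera (0.218 and 0.361, and 0.988 with an estimated correlation). Fasn, the fatty acid synthase gene, went from 37.1 ± 42.0 FPKM (SD, n = 12) to 6.41 ± 4.75 (n = 11) and fell by 2.04 ± 0.35 on the log2 scale (adjusted p = 2.07e-06), being lower at 6 of 6 times. Srebf1, which encodes the lipogenic factor SREBP1, went from 45.9 ± 34.1 to 10.7 ± 8.41 FPKM and fell by 1.95 ± 0.27. Cyp7b1, an oxysterol hydroxylase gene of bile acid synthesis, rose from 153 ± 87.2 to 416 ± 164 FPKM, by 1.68 ± 0.30 (adjusted p = 3.43e-06). Moxd1 rose from 29.1 ± 32.9 to 54.6 ± 18.9 FPKM, by 2.30 ± 0.53, and was higher at 5 of 6 times. Scand1 fell the most, from 23.3 ± 6.83 to 0.10 ± 0.14 FPKM, by 4.43 ± 0.11 (adjusted p = 9.08e-34). The mutant pairs examined below held 11.09 to 16.53 FPKM ad libitum and 7.31 to 17.95 restricted. A library cause was not tested for Scand1. Next to it stood Rplp1, Ccdc85b, Dpm3, Tpgs1 and Cldn3, which fell by 3.33 to 3.54. The mitochondrial transcripts mt-Tp and mt-Nd6 rose by 3.96 ± 0.29 and 3.92 ± 0.20, along with mt-Ti at 3.23 ± 0.28, Ugt2b38 at 1.94 ± 0.35 and Mup16 at 2.01 ± 0.55.

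Among lipid lists in WT, 9 of 17 fatty acid synthesis genes fell and none rose (8 adjusted over the list alone), Acacb by 1.30 ± 0.22 and Fads2 by 1.08 ± 0.24 among them. Of 24 cholesterol synthesis genes 11 fell and 1 rose (11 and 1 adjusted over the list alone), with Mvd down by 2.21 ± 0.32, Mvk by 1.85 ± 0.21 and Pmvk by 1.38. Of 14 lipid droplet genes 8 fell and 1 rose (the same numbers adjusted over the list alone), among them G0s2, an inhibitor of triglyceride lipase, by 2.32 ± 0.40, Fitm1 by 2.00 ± 0.21, Apoa4 by 1.87 ± 0.36 and Plin5 by 1.33 ± 0.17. For fatty acid oxidation 8 of 24 fell and 2 rose (7 and 2 adjusted over the list alone), with Fgf21, the hepatokine gene, at -1.51 ± 0.29. The bile acid list divided evenly, 5 of 15 rising and 5 falling (5 and 5 adjusted over the list alone), and so did glucose and glycogen, with 5 and 5 of 17 (4 and 5 adjusted over the list alone). In the latter Pcx, pyruvate carboxylase, fell by 1.46 ± 0.17 and Irs2 by 0.91. GC slope and opposite-strand reads moved with feeding in these libraries, and after a GC and length correction the differences were -1.08 for Fasn, -0.93 for Srebf1, -1.12 for Mvd, -0.88 for Mvk, -0.90 for Pcx, -1.49 for G0s2, -0.69 for Fitm1, 1.30 for Cyp7b1 and 3.04 for Moxd1, all still passing. Those of Nr0b2 (-1.36 to -0.37, adjusted p = 0.253), Slco1a1 (1.29 to 0.57) and Acaa1b (-1.46 to -0.46) no longer passed. On corrected values 7 fatty acid synthesis, 7 cholesterol synthesis, 7 lipid droplet, 5 oxidation, 2 glucose and 1 of the bile acid genes fell, and 1 lipid droplet and 1 bile acid gene rose.

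Of 18 core clock genes measured in WT, 4 rose and 3 fell (3 and 1 adjusted over the list alone). The period gene Per1 fell by 0.98 ± 0.15 and the output factor Dbp by 0.69 ± 0.29, while Nr1d2 rose by 0.84 ± 0.19, Rora by 0.64 ± 0.14 and Clock by 0.52 ± 0.09. After the GC and length correction Per1 was at -0.06, Dbp at 0.01 and Clock at 0.005, none of which passed, while Nr1d2 at 0.51 and Rora at 0.59 did. Arntl was at 0.12 ± 0.16 and Cry1 at -0.02. Of the male-biased liver genes 8 of 17 rose and none fell (5 adjusted over the list alone), with a median of 0.551, Cyp7b1, Ugt2b38 and Serpina1e (1.04 ± 0.45) among them. Ad libitum ZT8 replicate 1 stood apart, with Mup17 at 8.72, Cyp2b9 at 162.68 and Moxd1 at 0.0 FPKM. Moxd1 was also at 0.03 at most at ZT12 and ZT16 replicate 1 and at 0.47 at ZT20 replicate 2, against 25.69 or more in restricted libraries. The male-biased median was 0.412 to 0.708 with 1 library left out, which does not test these libraries together. Serpina1e was at 0.53 and no longer passed without ZT8 replicate 1. None of 8 female-biased genes passed by limma. Heat shock genes rose in 4 cases and fell in 2 of 13 (4 and 1 adjusted over the list alone): the chaperonin genes Hspd1 and Hspe1 rose by 0.75 each, and Hspb1, at -1.61 ± 0.25, was at -0.23 after the correction. In the ER stress list 2 of 18 rose and 3 fell (2 and 3 adjusted over the list alone), with Dnajb9 at 1.21 ± 0.27, and Atf5 at -0.96 turned to 0.51 after the correction. On corrected values 5 ER stress genes rose and none fell by limma, and the list's median turned from -0.148 to 0.286. Xenobiotic genes rose in 2 and fell in 4 of 16 cases (1 and 4 adjusted over the list alone), with Por, cytochrome P450 reductase, at -1.38 ± 0.22. Nrf2 genes rose in 1 and fell in 2 of 12 cases (1 and 0 adjusted over the list alone), Gclm at 0.50 ± 0.09 and Hmox1 at -0.43, the latter at 0.03 after the correction. Only Hp, haptoglobin, passed among 18 acute phase genes (1 adjusted over the list alone), at -1.24 ± 0.29, and it was at -0.56 and no longer passed after the correction. Corrected values gave 3 core clock, 5 male-biased and 3 heat shock genes up and none down, 2 Nrf2 genes up and 1 down, 1 xenobiotic gene down and 1 acute phase gene up by limma, and the core clock, Nrf2 and heat shock medians turned from -0.138, -0.131 and -0.078 to 0.066, 0.03 and 0.078.

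Markers of other cells also moved in WT. Erythroid genes fell in 3 of 5 cases, Hba-a1 by 3.06 ± 0.44. Adipocyte genes fell in 2 of 3, Cfd by 2.31 ± 0.31, and endothelial genes fell in 7 and rose in 2 of 13, Egfl7 at -0.96 and Stab1 at -0.85. Immune genes rose in 2 and fell in 3 of 11, the antigen presentation gene Cd74 at -1.13 ± 0.22. Stellate cell genes rose in 3 and fell in 4 of 12, Lum at 0.85 and Tgfb1 at -0.96. Bile duct genes had 1 of 3 up, Spp1 at 0.74, and 1 down. Hepatocyte genes rose in 2 and fell in 5 of 11, Cps1 at 0.72 and Apoa1 at -0.99, cell cycle genes fell in 2 of 5, and none of 9 pancreas genes passed. Adjusted over the list alone these counts were unchanged except for endothelial genes, 8 of which fell. After the correction 2 endothelial genes fell and none rose, 2 immune genes rose and none fell, and 1 stellate gene rose and 3 fell. There 2 bile duct genes rose, 4 hepatocyte genes rose and 2 fell, 1 cell cycle gene rose and 1 fell, and 2 erythroid and 2 adipocyte genes fell. The immune, hepatocyte, bile duct and pancreas medians turned from -0.08, -0.251, -0.014 and -0.258 to 0.109, 0.21, 0.329 and 0.016, and Cd74 and Egfl7 no longer passed.

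In WT the feeding contrast passed for 6378 of 9958 genes, 2848 up and 3530 down. After the GC and length correction it passed for 3752, 1908 up and 1844 down, and a change of scaling raised the share that rose from 44.7% to at most 51.1%. No list passed in camera, the lowest adjusted p being 0.181 for male-biased genes and 0.988 with an estimated correlation. Camera's direction was up, against other genes, for the core clock, ER stress, xenobiotic, female-biased and pancreas lists, whose medians were below 0, while the heat shock and bile duct lists had medians below 0 and means above it.

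In Bmal1LKO the fatty acid synthesis list fell with restricted feeding. Its median was -0.802 over 17 genes and camera gave an adjusted p of 1.44e-16, with adjusted p = 0.0383 with an estimated correlation, which was 0.0623 on values corrected for GC and length. Of its members 1 fell over all genes tested (2 on corrected values) and 12 fell adjusted over the list alone. Me1, the malic enzyme gene that supplies NADPH, went from 12.9 ± 6.42 to 2.33 ± 0.83 FPKM (SD, n = 6 each) and fell by 1.91 ± 0.36 (adjusted p = 0.00862), lower at 6 of 6 times. With only the Bmal1LKO groups in the fit its adjusted p was 0.0731. Fasn went from 34.3 ± 11.2 to 10.3 ± 9.12 FPKM, a difference of -1.87 ± 0.48 (adjusted p = 0.106), and Scd1, the stearoyl-CoA desaturase gene, differed by -2.64 ± 0.58 (adjusted p = 0.0517). Beyond Me1, 3 genes passed, named here after their values were seen: Trat1 rose by 2.65 ± 0.34, Wif1 by 1.05 ± 0.20, and the immediate early gene Nr4a1 fell by 1.25 ± 0.23. Other list directions in camera were lost with an estimated correlation. Cholesterol synthesis genes were lower (adjusted p = 2.36e-06, and adjusted p = 0.542 with an estimated correlation) with no member passing, acute phase and male-biased genes were higher (0.00217 and 0.00272, and adjusted p = 0.636 with an estimated correlation for both), and Nrf2, endothelial and glucose genes were lower (0.00217, 0.0107 and 0.0324, and adjusted p = 0.519 to 0.542 with an estimated correlation). In all 4 genes passed, and 1017 had an unadjusted p under 0.05. The count was 103 with no filter, 938 with library weights, 32 with only these groups in the fit, 115 without the 8 libraries with pancreas reads, and from 1, without ad libitum ZT4, to 13, without ad libitum ZT16, with 1 library left out. Scaling each library to the same sum shifted the median of all genes by -0.15 and gave 3 up and 9 down. The bile acid and hepatocyte lists had medians above 0 and camera's direction down.

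In CryDKO 2 genes passed with feeding, named after their values were seen. Tbx3os1 fell by 0.50 ± 0.10 and Nup62cl by 0.53 ± 0.11 (adjusted p = 0.0403 each), and 564 had an unadjusted p under 0.05. Fasn differed by 0.32 and Cyp7b1 by -0.22 ± 0.35. The bile acid list was lower with a median of -0.224 (adjusted p = 0.000188, and adjusted p = 0.0398 with an estimated correlation, which was 0.411 on values corrected for GC and length), though no member passed; Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by -0.72 ± 0.42. Acute phase (median 0.454), ER stress (0.395), heat shock, cell cycle and pancreas (1.341) genes were higher, and xenobiotic (-0.361), fatty acid oxidation and male-biased genes lower, at camera adjusted p of 1.93e-06 to 0.00322. None of these directions held (adjusted p = 0.134 to 0.538 with an estimated correlation). Saa1 reached 41908 FPKM in the restricted library of ZT3 against 3147 in the next, and pancreas Clps reached 192 FPKM in the restricted libraries and 0 in the ad libitum ones. With 1 library left out the count ran from 0, without ad libitum ZT9 for example, to 28, without restricted ZT21, and it was 26 with no filter, 473 with library weights and 0 with only these groups in the fit. Scaling each library to the same sum gave 1 up and 4 down. Median, mean and camera differed in sign for the glucose, endothelial and hepatocyte lists, with means of 0.017, 0.011 and 0.009.

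In ReverbLDKO 4 of 8 genes known as female-biased in mouse liver were lower under restricted feeding and 5 of 17 male-biased ones higher, though neither list passed camera throughout (adjusted p = 0.072 and adjusted p = 0.141 with an estimated correlation). Cyp2a4, a steroid hydroxylase gene, went from 94.1 ± 62.5 to 0.53 ± 0.53 FPKM (SD, n = 8 each) and fell by 5.25 ± 0.39 (adjusted p = 5.36e-14), lower at 8 of 8 times. Cyp2b9 went from 61.0 ± 64.2 to 1.64 ± 1.91 FPKM and fell by 3.74 ± 0.79, lower at 7 of 8 times. Cyp7b1 rose from 89.8 ± 41.5 to 274 ± 69.8 FPKM, by 1.72 ± 0.35, and Moxd1 from 34 ± 23.3 to 98.0 ± 35.5, by 2.28 ± 0.63, both at 8 of 8 times. The female-biased list (6 fell adjusted over the list alone) had a median of -1.03, and Cyp2b13 and Abcd2 were the others that fell, at -1.62 ± 0.40 and -1.09 ± 0.31. The male-biased list (7 rose adjusted over the list alone) had a median of 0.847, with Serpina1e at 2.23 ± 0.54, Ugt2b38 at 1.48 ± 0.41 and the complement gene C6 at 1.08 ± 0.25 among them. At the preset correlation camera gave 2.5e-08 and 8.63e-10. Opposite-strand reads were lower with restricted feeding here, with mt-Nd6 falling by 3.11 ± 0.24 and mt-Tp by 2.49 ± 0.35.

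Further lists moved in ReverbLDKO. Acute phase genes rose in 4 of 18 cases (8 adjusted over the list alone, 13 on corrected values), Orm1 by 1.40 ± 0.37 and the fibrinogen genes Fga and Fgg by 0.95 ± 0.25 and 0.90 ± 0.23 (camera adjusted p = 8.63e-10, and adjusted p = 0.206 with an estimated correlation). Saa1 stood at 9196 and 16119 FPKM in the restricted libraries of ZT15 and ZT18 and at 699 at most in the 6 others, and Orm1, Fga and Fgg no longer passed without restricted ZT18 or without ad libitum ZT24. Nrf2 genes fell in 4 of 12 cases (5 adjusted over the list alone), Gstm3 by 1.33 ± 0.28 and Nqo1, a quinone reductase gene, by 1.13 ± 0.22 (6.42e-06, and adjusted p = 0.141 with an estimated correlation). Lipid droplet genes fell in 4 and rose in 1 of 14 cases (6 and 1 adjusted over the list alone): Plin4 fell by 1.52 ± 0.21 and the fatty acid transporter gene Cd36 by 1.08 ± 0.30, while Lpl, lipoprotein lipase, rose by 0.83 ± 0.17 (0.000476, and adjusted p = 0.206 with an estimated correlation). Of the fatty acid synthesis genes Me1 alone fell, from 23.1 ± 5.25 to 10.1 ± 4.47 FPKM, with 3 falling adjusted over the list alone, or 1 on corrected values (0.00313, and adjusted p = 0.378 with an estimated correlation). Tef and Per1 of the core clock fell by 0.69 ± 0.18 and 0.64 ± 0.18, the latter at -0.46 and no longer passing after the GC and length correction, as were Acaa1b, Fitm1, Slc10a1, Srxn1 and Hspd1. Heat shock, bile duct, ER stress and bile acid genes were higher and immune, xenobiotic and pancreas genes lower in camera at adjusted p of 0.00512 to 0.0497, and none held (adjusted p = 0.141 to 0.597 with an estimated correlation). The bile acid direction was at 0.205 on corrected values. Hamp2 fell by 2.33 ± 0.58 and Cdh1, E-cadherin, rose by 1.30 ± 0.26. In all 332 genes passed, 108 up and 224 down. The count was 2381 with only these groups in the fit, 4136 with library weights, 1056 with each library scaled to the same sum and 172, without restricted ZT24, to 298 with 1 library left out. The share that rose was 32.5%, against 46.5% with median-of-ratios scaling, 46.3% with voom and 4.9% with the same sum, which shifted the median of all genes by -0.116.

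As the mean of 4 genotypes, 13 of 17 fatty acid synthesis genes fell under restricted feeding (15 adjusted over the list alone), with Fasn at -1.09 ± 0.21, Scd1 at -1.03 ± 0.25, Me1 at -0.86 ± 0.16 and Srebf1 at -0.84 ± 0.16, and 11 of 18 acute phase genes rose (12 adjusted over the list alone), with Saa1 at 1.40 ± 0.44, Saa2 at 1.48 ± 0.49 and Orm2 at 1.12 ± 0.38. Camera gave adjusted p of 6.61e-06 and 8.24e-05 (0.516 with an estimated correlation for both). Lipid droplet genes fell in 8 and rose in 1 of 14 cases (9 and 1 adjusted over the list alone) with G0s2 at -1.12 ± 0.24 and Fitm1 at -1.04 ± 0.13, Nrf2 genes fell in 7 of 12, male-biased genes rose in 8 of 17 and heat shock genes in 4 of 13, the latter 3 lists with the same counts adjusted over the list alone. All 4 were lost with an estimated correlation (adjusted p = 0.516), though fry gave 0.000248 to 0.0328. On corrected values 10 fatty acid synthesis, 7 lipid droplet and 3 Nrf2 genes fell, and 10 acute phase, 6 male-biased, 2 heat shock and 1 of the lipid droplet genes rose. In WT the 1 acute phase gene that passed fell. Saa1 stood apart in restricted CryDKO ZT3, Bmal1LKO ZT24 (7839 FPKM) and ReverbLDKO ZT15 and ZT18; Saa1, Saa2 and Orm2 passed with any 1 library left out and not with library weights (adjusted p = 0.0776, 0.126 and 0.277). Of markers of other cells 3 of 3 adipocyte, 5 of 13 endothelial, 4 of 12 stellate and 3 of 11 immune genes fell (1, 1, 2 and 3 on corrected values), and 2 of 3 bile duct, 1 stellate and 1 immune gene rose. Moxd1 at 1.53 ± 0.32, Cyp7b1 at 1.02 ± 0.18, Hamp2 at -1.31 ± 0.29, Lgals1 at -1.14 ± 0.18, Acaa1b at -1.10 ± 0.16, Abcc3 at -1.06 ± 0.17 and Fgf21 at -0.87 ± 0.17 passed as well. Of 3786 genes that passed, 1449 rose and 2337 fell, and 1570 passed after the GC and length correction. The share that rose was 38.3%, against 16.4% with each library scaled to the same sum. Camera's direction was up for the cell cycle, pancreas and hepatocyte lists, whose means were below 0.

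Genes passing in both WT and ReverbLDKO numbered 73 that rose, where independent lists would share 30.9, and 126 that fell, against 79.4. Fisher's exact test (p = 3.57e-17 and 1.1e-10) takes genes, not libraries, as independent. In ReverbLDKO 26 that rose in WT fell, and 5 that fell in WT rose. The median GC slope also fell in both. After the GC and length correction 82 rose in both, against 45.4 with 44 opposite, and 63 fell, against 46.2 with 28 opposite. With each library scaled to the same sum 36 rose in both and 123 rose in WT and fell in ReverbLDKO. Wif1 rose in WT, Bmal1LKO and ReverbLDKO and was the only gene past the threshold in at least 3 genotypes in the same direction. The feeding effect differed between genotypes for 4695 genes, 2499 after the GC and length correction. The smallest p-values belonged to Scand1 (adjusted p = 1.97e-27), mt-Nd6, Ccdc85b, Tpgs1, the AP-1 gene Jund, mt-Tp, Csnk1g2 and Zfp771 (2.24e-14), of which mt-Nd6 and mt-Tp moved with the opposite-strand reads in WT and ReverbLDKO. For Scand1 a library cause was not tested.

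**Figure D2:**
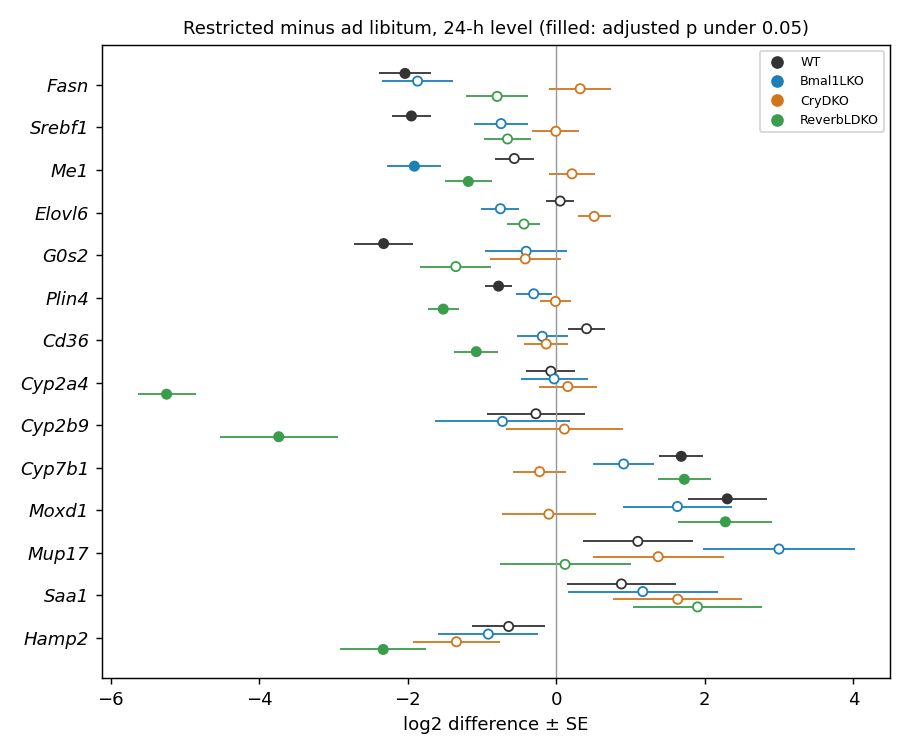
Restricted minus ad libitum log2 difference ± SE (horizontal) for 14 named genes, by genotype, filled where the adjusted p was under 0.05. Fasn lies at -2.04 in WT, Cyp2a4 at -5.25 in ReverbLDKO, and Cyp7b1 at 1.68 and 1.72 in WT and ReverbLDKO.

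Against WT, Bmal1LKO livers had more mRNA of Sult1e1, Lpl and the clock gene Npas2 and less of Mup17, Nat8 and 10 of 16 xenobiotic metabolism genes. Sult1e1, an oestrogen sulfotransferase gene, stood at 95.2 ± 47.7 FPKM (SD, n = 12) against 2.50 ± 2.34 (n = 23) and rose by 4.88 ± 0.33 (adjusted p = 1.46e-16). Lpl was at 38.8 ± 13.0 against 3.40 ± 1.41 FPKM, a rise of 3.17 ± 0.12. Loxl4 rose by 2.54 ± 0.11, Defb1 by 2.68 ± 0.22, Gstm3 by 2.39 ± 0.20 and Ntrk2 by 2.39 ± 0.08. Mup17, a major urinary protein gene, fell from 2598 ± 1781 to 217 ± 287 FPKM, by 3.99 ± 0.63, with Nat8 by 3.17 ± 0.20, Ces1d by 2.93 ± 0.21 and Rgs16 by 2.33 ± 0.34. In the core clock list 6 rose and 5 fell of 18 (6 and 5 adjusted over the list alone): Npas2 by 1.80 ± 0.10 and Cry1 by 1.38 ± 0.09 up, Nr1d2 by 1.37 ± 0.16, Nr1d1 by 0.99 ± 0.16 and Ciart by 0.99 ± 0.15 down. Xenobiotic genes fell in 10 and rose in 2 of 16 cases (10 and 2 adjusted over the list alone), Cyp2a5 by 2.00 ± 0.21 and the bilirubin transferase gene Ugt1a1 by 1.47 ± 0.11 down, Cyp2c55 by 2.09 ± 0.12 up (camera adjusted p = 5.14e-07, and adjusted p = 0.0675 with an estimated correlation). Fatty acid oxidation genes fell in 13 and rose in 1 of 24 cases (14 and 1 adjusted over the list alone), Acot1 by 1.00 ± 0.21 down and Pdk4 by 1.1 ± 0.19 up (3.09e-07, and adjusted p = 0.239 with an estimated correlation). Of the fatty acid synthesis genes 5 of 17 fell (5 adjusted over the list alone, 9 on corrected values), Thrsp by 1.36 ± 0.23 and Me1 by 1.01 ± 0.22 (0.00446, and adjusted p = 0.547 with an estimated correlation). Bile duct genes rose in 3 of 3 cases, Spp1 by 1.04 ± 0.18 and Sox9 by 0.91 ± 0.10 among them, and stellate genes in 8 of 12, Col3a1 by 0.58 ± 0.13 (3 and 8 adjusted over the list alone, 2 and 5 on corrected values; adjusted p = 0.0675 and adjusted p = 0.528 with an estimated correlation). Heat shock genes fell in 4 of 13 cases (5 adjusted over the list alone) and ER stress genes fell in 4 and rose in 1 of 18 (4 and 1 adjusted over the list alone), Herpud1 by 1.26 ± 0.17 and Asns by 1.08 ± 0.16 down (adjusted p = 0.357 and adjusted p = 0.528 with an estimated correlation). Alb, albumin, fell by 1.30 ± 0.09. Adipocyte genes fell in 2 of 3 cases.

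The Bmal1LKO contrast passed for 2721 genes, 1959 up and 762 down. The share that rose was 72%, against 54% with median-of-ratios scaling, 59.2% with voom and 93.8% with the same sum, which shifted the median of all genes by 0.146. The count was 4357 without the 8 libraries with pancreas reads and 1677 with only these groups in the fit. Glucose, endothelial, erythroid, Nrf2 and hepatocyte genes had medians above 0 and camera's direction down, and the bile acid list a median of -0.049 and a mean of 0.028.

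Against WT, CryDKO livers had more mRNA of Dbp, Ciart and Cyp2b9 and less of Nnmt, Me1 and Moxd1. Dbp, a circadian output factor, stood at 31.1 ± 8.12 FPKM (SD, n = 16) against 9.48 ± 15.2 (n = 23) and rose by 2.65 ± 0.22 (adjusted p = 7.8e-14). Of 18 core clock genes 13 rose and 3 fell (13 and 4 adjusted over the list alone), with Ciart at 2.19 ± 0.14, Nr1d1 at 1.55 ± 0.14, Per1 at 1.34 ± 0.12, Per3 at 1.26 ± 0.10 and Tef at 1.16 ± 0.12, and Nfil3 at -0.62 ± 0.14 (camera adjusted p = 0.000477, and adjusted p = 0.1 with an estimated correlation). Cyp2b9, a female-biased gene, stood at 90.2 ± 53.8 against 14.8 ± 37.3 FPKM and rose by 4.40 ± 0.52. Nnmt, nicotinamide N-methyltransferase, fell from 267 ± 269 to 29.5 ± 71.1 FPKM, by 4.87 ± 0.30, and Me1 from 14.6 ± 10.9 to 1.80 ± 0.77, by 2.23 ± 0.20. Fam25c fell by 4.92 ± 0.24, Moxd1 by 4.25 ± 0.41, Ugt2b38 by 3.40 ± 0.27 and Serpina12 by 3.22 ± 0.25. Ugt1a9 rose by 3.04 ± 0.16, Cyp4a14 by 3.16 ± 0.58 and Cyp2c39 by 2.57 ± 0.32.

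Heat shock genes fell in 11 and rose in 1 of 13 cases in CryDKO (12 and 1 adjusted over the list alone), Hspa8 by 2.76 ± 0.20 and Hspe1 by 1.00 ± 0.19 (camera adjusted p = 0.00166, and adjusted p = 0.943 with an estimated correlation). Male-biased genes fell in 10 and rose in 2 of 17, Mup20 by 2.17 ± 0.27, and lipid droplet genes fell in 8 and rose in 2 of 14, Fitm1 by 2.39 ± 0.17 and Cidec by 1.20 ± 0.26. ER stress genes fell in 10 and rose in 1 of 18, and endothelial genes rose in 9 and fell in 1 of 13, Stab2 by 0.75 ± 0.12. Counts of these lists were the same adjusted over the list alone, and camera gave 0.0498 for each (adjusted p = 0.959 with an estimated correlation), or 0.109 to 0.155 on values corrected for GC and length. Of 8 female-biased genes 6 rose and 1 fell, and of 18 acute phase genes 9 fell, Saa1 by 3.0 ± 0.57 and Orm3 by 2.04 ± 0.27 (the same numbers adjusted over the list alone), without a call in camera (adjusted p = 0.212 and 0.0644). Fatty acid synthesis genes rose in 6 and fell in 5 of 17 (6 and 5 adjusted over the list alone; 4 and 7 on corrected values), Fasn by 1.36 ± 0.27 and Srebf1 by 0.92 ± 0.21 up. Xenobiotic genes rose in 7 and fell in 3 of 16 (7 and 3 adjusted over the list alone, 8 and 1 on corrected values), Cyp3a11 by 2.54 ± 0.24 and Por by 1.54 ± 0.17 up and Cyp2a5 by 2.67 ± 0.19 down. Of markers of other cells, 3 of 5 erythroid genes rose and 2 fell, 5 of 11 immune genes fell, and 2 of 12 stellate genes rose and 4 fell, without a call in camera (adjusted p = 0.113 to 0.719). In all 6514 genes passed, 3429 up and 3085 down. The share that rose was 52.6%, against 69.4% with the same sum of FPKM, which shifted the median of all genes by 0.154. Median, mean and camera's direction differed in sign for the fatty acid synthesis, bile acid, oxidation and adipocyte lists, with means of -0.002, 0.052, 0.112 and -0.276.

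Against WT, ReverbLDKO livers had more mRNA of Arntl and Npas2, which REV-ERB proteins are known to repress, and less of Mup17 and 19 of 24 cholesterol synthesis genes. Arntl stood at 12.6 ± 2.28 FPKM (SD, n = 16) against 6.62 ± 4.53 (n = 23) and rose by 1.27 ± 0.12 (adjusted p = 2.77e-11), and Npas2 rose by 1.67 ± 0.09. Of the core clock list 14 rose and 1 fell (15 and 1 adjusted over the list alone), Dbp by 1.37 ± 0.22, Cry1 by 0.97 ± 0.08 and Nfil3 by 0.86 ± 0.14 up (camera adjusted p = 5.03e-05, and adjusted p = 0.052 with an estimated correlation). Per1, at 0.31 ± 0.12, was at -0.01 after the GC and length correction, and Tef and Clock no longer passed either. Cyp51, lanosterol demethylase, fell from 56.0 ± 26.6 to 14.9 ± 8.81 FPKM, by 1.83 ± 0.21. In all 19 of 24 cholesterol synthesis genes fell and none rose (19 adjusted over the list alone), Msmo1 by 1.78 ± 0.25, Pmvk by 1.42 ± 0.17 and Nsdhl by 1.39 ± 0.20 (1.54e-06, and adjusted p = 0.39 with an estimated correlation). Cyp7a1 fell by 1.61 ± 0.27. Mup17 fell from 2598 ± 1781 to 42.93 ± 45.04 FPKM, by 6.04 ± 0.58, with Mup9 by 3.85 ± 0.41 and Nat8 by 2.68 ± 0.19. Loxl4 rose by 3.19 ± 0.10, Lpl by 2.29 ± 0.11 to 21.3 ± 9.57 FPKM, Cyp17a1 by 2.80 ± 0.25, Obp2a by 2.48 ± 0.22 and Cyp2a5 by 2.24 ± 0.19.

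Glucose and glycogen genes rose in 10 of 17 cases in ReverbLDKO (10 adjusted over the list alone), Igfbp1 by 2.13 ± 0.36, Irs2 by 1.1 ± 0.14 and Pcx by 0.80 ± 0.13 (camera adjusted p = 0.00661, and adjusted p = 0.39 with an estimated correlation). Female-biased genes rose in 5 and fell in 1 of 8 (6 and 1 adjusted over the list alone), and male-biased genes fell in 10 and rose in 1 of 17 (11 and 1 adjusted over the list alone), Cyp4a12a by 2.06 ± 0.24 and Serpina1e by 1.72 ± 0.35 (0.00653 and 0.00923, and adjusted p = 0.39 and adjusted p = 0.627 with an estimated correlation), the latter list at 0.0629 on values corrected for GC and length. Heat shock genes fell in 11 and rose in 1 of 13 (12 and 1 adjusted over the list alone) and ER stress genes fell in 14 and rose in 1 of 18 (14 and 3 adjusted over the list alone), Hspb1 by 1.04 ± 0.20, Creld2 by 1.45 ± 0.29 and Manf by 1.31 ± 0.25 down (0.0033 and 0.00448, and adjusted p = 0.39 and adjusted p = 0.559 with an estimated correlation). Cell cycle genes rose in 4 and fell in 1 of 5 (the same adjusted over the list alone), Ccnd1 by 0.91 ± 0.17 and Mcm6 by 0.87 ± 0.09 up (0.0268, and adjusted p = 0.39 with an estimated correlation). Srebf1 and Fasn rose by 1.41 ± 0.21 and 1.05 ± 0.27, and Saa1 fell by 2.15 ± 0.57. Of markers of other cells, erythroid genes rose in 4 of 5 cases, with a median of 1.464, stellate genes in 6 of 12 and bile duct genes in 2 of 3. Endothelial genes rose in 7 (4 on corrected values) and fell in 3 of 13. Adjusted over the list alone the counts were the same. None of these 4 lists passed camera (adjusted p = 0.135 to 0.39), though erythroid genes were at 0.0243 on corrected values (adjusted p = 0.436 with an estimated correlation). In all 5758 genes passed, 3001 up and 2757 down, a share of 52.1% that rose against 81% with the same sum of FPKM, which shifted the median of all genes by 0.211. The lipid droplet and immune lists had medians of -0.038 and -0.098 and means of 0.09 and 0.045.

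**Figure D3:**
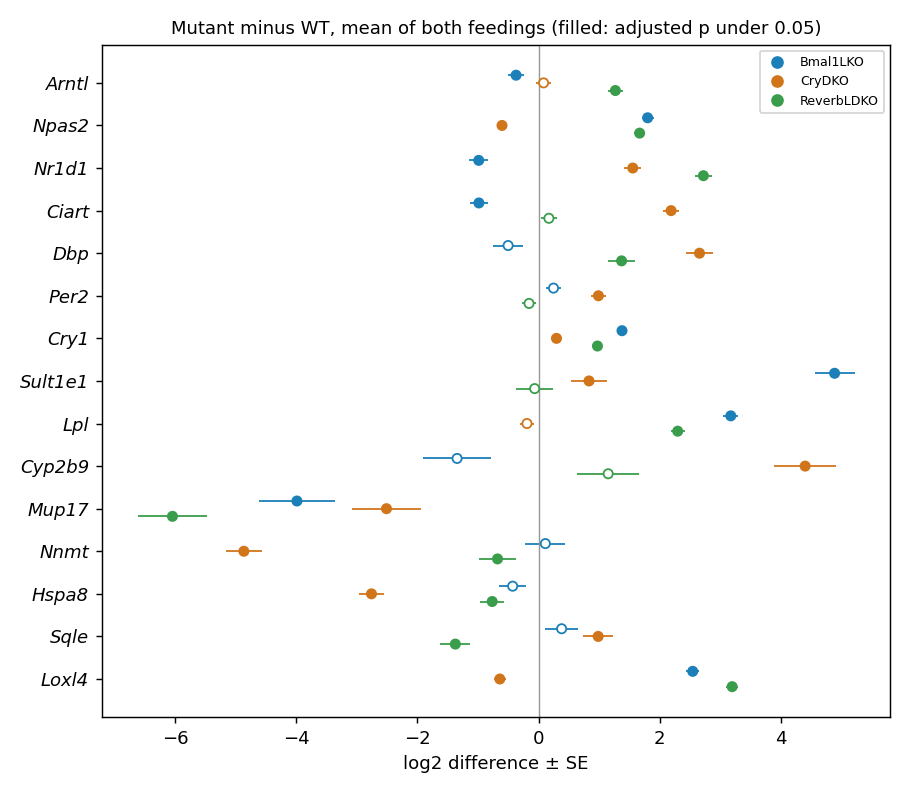
Mutant minus WT log2 difference ± SE (horizontal), mean of both feedings, for 15 named genes in 3 mutants, filled where the adjusted p was under 0.05. Sult1e1 lies at 4.88 in Bmal1LKO, Nnmt at -4.87 in CryDKO and Mup17 at -6.04 in ReverbLDKO.

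Clock genes were rhythmic over 24 h in WT under both feedings. Under ad libitum feeding Nr1d1 had an amplitude of 2.38 on the log2 scale and peaked at ZT7.9 (adjusted p = 7.86e-13), Cry1 one of 1.31 at ZT18.9, Arntl 1.33 at ZT22.6, Dbp 2.16 at ZT10.7 and Per2 1.13 at ZT13.4. Clpx, Cldn1 and the lipogenic gene Thrsp, with 2.52 at ZT14.3, were among the smallest p-values. Under restricted feeding Cry1 had 1.44 at ZT19.2 (3.04e-13), Arntl 1.71 at ZT22.2, Nr1d1 1.72 at ZT7.2, Dbp 1.85 at ZT10.4 and Chka 1.34 at ZT22.9, while Per1 had 0.17 (adjusted p = 0.658) against 0.90 ad libitum (0.000129). Of 18 core clock genes 17 were rhythmic ad libitum and 13 under restriction, and of 13 heat shock genes 10 and 8. In all 2957 genes were rhythmic ad libitum and 1990 under restriction. These counts were 167 and 61 with only 1 group in the fit, and 5365 ad libitum with library weights; with 1 library left out the ad libitum count was as low as 1561, without ZT4 replicate 1, and the restricted count ran from 951, without ZT12 replicate 2, to 3542, without ZT16 replicate 1. No gene passed limma's test of a difference in rhythm between the feedings (lowest adjusted p 0.192, Hsp90b1), with 882 at an unadjusted p under 0.05, 248 passing with library weights, none with voom, 2 with no filter and 457 without restricted ZT16 replicate 1.

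**Figure D4:**
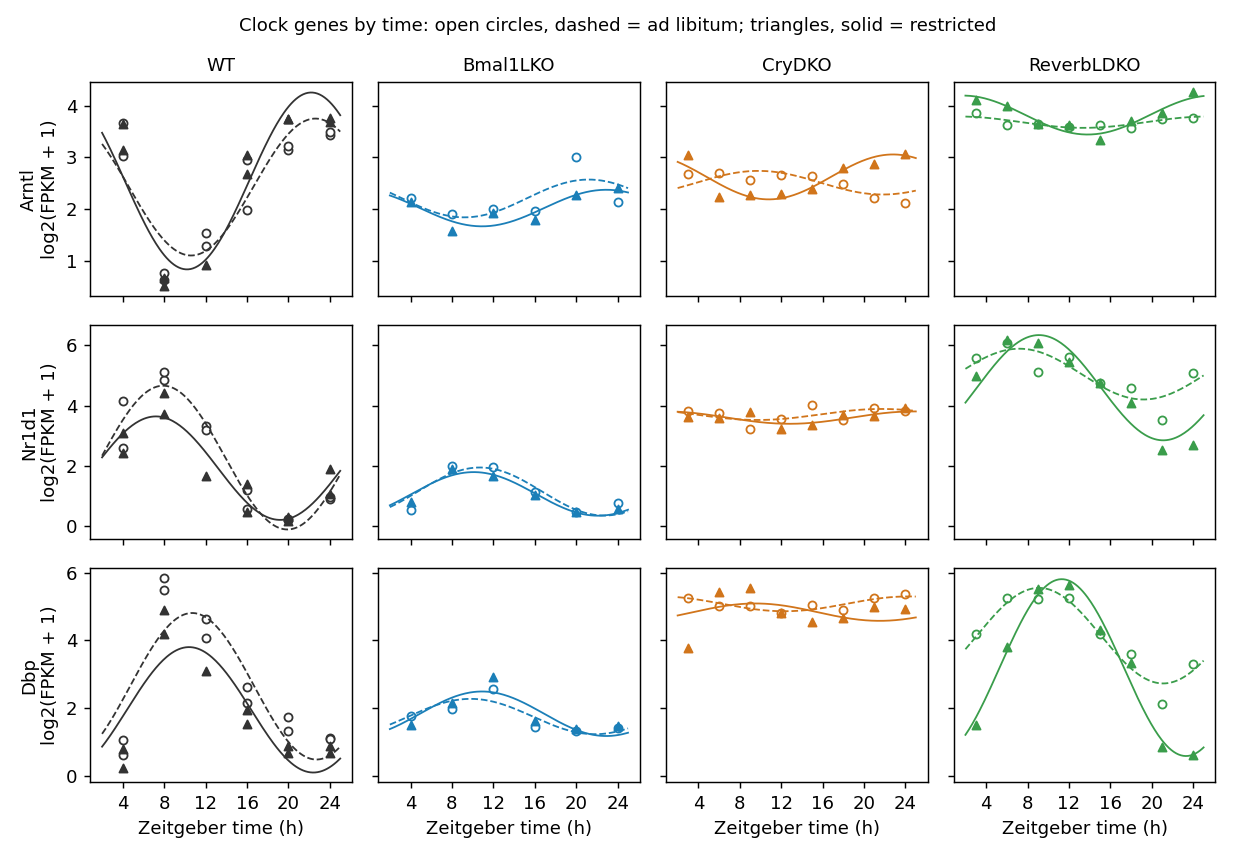
Arntl, Nr1d1 and Dbp as log2(FPKM + 1) (vertical) against zeitgeber time in hours (horizontal), 1 point per library, with fitted curves for both feedings and 4 genotypes. Fitted Nr1d1 amplitudes are 2.38 and 1.72 in WT and 0.84 and 1.75 in ReverbLDKO, ad libitum and restricted.

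In the mutants clock rhythms were mostly below the threshold. In ad libitum Bmal1LKO 1 of 18 core clock genes passed, Per1 with an amplitude of 1.16 at ZT14.1 (adjusted p = 0.0282), as did the sterol transporter gene Abcg5 and Grk5, 3 in all with 531 at an unadjusted p under 0.05. Under restriction 51 genes passed and no clock gene, led by Soat2 and Abcg5 (0.00498 each), Abcg8, Dnajc3, Rcan1 and Hoga1. That count was 200 after the GC and length correction, 4 with only this group in the fit, 5 with both, and 1, without ZT20, to 41 with 1 library left out. In ad libitum CryDKO 5 passed, Ddah1 at 1.48 and ZT5.8 and Igkv6-32 among them. Under restriction 720 passed, none in the core clock list by limma, led by Decr2 at 1.22 and ZT13.1 (1.93e-07), Acot12 at 1.09 and ZT12.1, Hsd17b11, Pcp4l1, Inca1 and Cyp2e1; 8 of 13 heat shock and 11 of 18 acute phase genes were among them. With only this group in the fit none passed, and without ZT12 302 did. In ReverbLDKO 3 genes passed ad libitum, Cyp2a4, Slc13a2 and Pcsk4. Under restriction 393 passed, with 8 core clock genes: Nr1d1 at 1.75 and ZT9.1 (6.03e-06), Dbp at 2.61 and ZT11.3, Ciart at 1.57 and ZT13.4, Per1 at 1.07 and ZT16.2, Per2 at 0.97 and ZT18.1, Per3 at 0.74, Tef at 1.09 and Cry1 at 0.57. Ad libitum amplitudes there were 0.84 for Nr1d1 and 1.41 for Dbp, and Gde1, Cldn1, St3gal5 and Aifm2 were also rhythmic under restriction. The restricted count was 801 after the GC and length correction, 668 with only this group in the fit, 797 without the 3 doubted libraries, 3466 with library weights, and 204, without ZT9, to 299 with 1 library left out.

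Whether rhythms differed between feedings was tested directly. In CryDKO 130 genes differed: Decr2 had 0.43 at ZT4.2 ad libitum against 1.22 at ZT13.1 (adjusted p = 8.85e-06), Ddah1 1.48 at ZT5.8 against 1.13 at ZT12.7, and Acot1 0.79 at ZT5.1 against 1.79 at ZT13.9 (0.0038), with Acot12, Meiob and Pcp4l1 besides. The count was 365 after the GC and length correction, 2 with only these groups in the fit and from 37, without ad libitum ZT24, to 291, without restricted ZT6, with 1 library left out. In ReverbLDKO no gene passed in limma (lowest adjusted p 0.785), with 280 at an unadjusted p under 0.05, 912 passing with library weights and 66 with only these groups, so the greater number of rhythmic clock genes under restriction was not shown to be a difference between feedings. In Bmal1LKO none passed either, with 102 at an unadjusted p under 0.05 and 117 passing with no filter.

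Rhythms that differed from WT numbered 38 in Bmal1LKO, among them Clpx (adjusted p = 1.39e-07), Cry1, Mreg, Mad2l2 and Cldn1. In CryDKO 467 differed, among them Cry1 and Nr1d1 (7.65e-09 each), Clpx, Mreg and Thrsp, and in ReverbLDKO 107, led by Clpx (1.32e-07), Chka, Mreg, Cry1 and Arntl. Without the 8 libraries with pancreas reads, 4 of them WT libraries of ZT16, these counts were 1783, 2534 and 2093. All 9 pancreas genes measured were rhythmic in ad libitum WT, where Clps reached 661 FPKM at ZT16, and none in the other groups.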

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

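The tests that weigh explanations for the 3 patterns below were chosen only after the result was seen. The splits of the samples at the end were planned.

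A single library lay far from the others of its group in 12 of 96 sets of values, where 16 measures were examined in the 6 mutant groups. Chance flags about 1 in 20 groups. Saa1 stood at 41907.84 FPKM at ZT3 in restricted CryDKO (next library 3146.58), at 2161.33 at ZT21 in ad libitum CryDKO (231.58) and at 7838.71 at ZT24 in restricted Bmal1LKO (2619.34). Mup17 stood at 1024.96 at ZT24 in restricted Bmal1LKO (419.96), and Arntl at 7.09 at ZT20 in ad libitum Bmal1LKO (3.67). Moxd1 stood at 2.02 at ZT21 in ad libitum CryDKO (0.86) and at 1.88 at ZT6 in restricted CryDKO (0.23). Cyp2a4 stood at 0.49 at ZT20 in ad libitum Bmal1LKO (0.06) and at 1.64 at ZT24 in restricted CryDKO (0.37). The mitochondrial percentage was 10.01 at ZT12 in ad libitum CryDKO (8.17). In ad libitum ReverbLDKO the GC slope was -0.037 at ZT24 (0.111) and the length slope -0.036 at ZT9 (0.032).

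By tests of the difference itself, the feeding effect differed between genotypes for 4695 genes, led by Scand1 and mt-Nd6, the rhythm differed between feedings in CryDKO for 130, led by Decr2, and it differed from WT for 38 in Bmal1LKO, 467 in CryDKO and 107 in ReverbLDKO.

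Many genes differ between feedings in WT, which is weighed first. A trend with GC content or gene length as the whole cause is argued against by the 3752 genes that pass after the correction, where the highest count under shuffled labels was 1714. A library difference seen in opposite-strand reads is argued against as the whole cause by the direction in ReverbLDKO, where these reads go the opposite way between feedings and 60.7% of those genes kept the direction they had in WT (58.6 to 62.1% with 1 library left out). For the 1475 genes that go the opposite way library and feeding cannot be told apart, being tied in either genotype. A feeding effect shared by the other genotypes may contribute and cannot be told apart either, as 47.8% went the same way in CryDKO (45.1 to 51% with 1 left out) and 47.4% in Bmal1LKO (41.6 to 55.3%).

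In another pattern, 4 of 8 female-biased genes tested, out of 18 listed, are lower and 5 of 17 male-biased genes higher under restricted feeding in ReverbLDKO, though neither list passed camera with an estimated correlation (adjusted p = 0.072 and adjusted p = 0.141). The library difference in opposite-strand reads would put the male-biased median in WT below 0. That median was 0.551 (0.412 to 0.708 with 1 library left out). Whether it rests on the ad libitum libraries low in Moxd1 together was not tested, so this explanation stays open. For female-biased genes, at -0.108 (-0.331 to 0.124), it cannot be told apart from feeding. Reads shared between paralogs are argued against by Cyp2a4 at no less than 0.92% of Cyp2a5 in any ad libitum library and no more than 0.17% in any restricted one. A single library is argued against by the female-biased median, which was -1.025 and no higher than -0.906 with any 1 library left out. That does not test ad libitum ZT21 and ZT24 together, where Moxd1 was lowest and Cyp2b9 highest. An effect of feeding was not tested apart from these and stays open.

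In the last pattern weighed, restricted WT libraries carry genes that stand apart in the ad libitum library of the same time and replicate number. Such genes, at 5 FPKM or more and at least 2 times the highest other ad libitum library, numbered 29 at ZT8 replicate 1, 21 at ZT16 replicate 1 and 1639 at ZT16 replicate 2, and the restricted partner held 51.7, 45.9 and 30.7% of their excess (median), while other restricted libraries held at most 9.8%; of the mutant pairs, Bmal1LKO ZT16 had 48% of the excess of 23 genes in its partner and at most 10.9% elsewhere, the partner was not highest in the 3 other Bmal1LKO pairs or in CryDKO, and the share was 0.0 in ReverbLDKO. A batch of the replicate number is argued against by 3.7%, the highest share at its other times. The time of day is argued against by 4.6%, the highest in the other replicate of the same time. Of genes at 20 FPKM or more ad libitum, 11 of 1977, 20 of 2142 and 68 of 2782 were low in the partner. Low was under 20.3, 18.2 and 4.9% (lower quartiles of the share 40.6, 36.3 and 9.7%), set after 5% found only 2 in 2 pairs. A loss in all restricted WT libraries, as for Scand1, would give such genes too. Mixed reads or libraries and RNA or tissue shared before library preparation stay open, with shares of 51.7 and 45.9% in replicate 1. The 30.7% at ZT16 replicate 2 cannot decide, since the FPKM were not rescaled. That ad libitum library summed to 1097495 FPKM, against 419016 to 566518 in the other ad libitum WT libraries. Its partner summed to 698391, the highest restricted WT sum. A shared cage or litter was not tested, and RNA shared in this way could shrink the WT feeding difference.

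Other splits of the samples were made by shuffling feeding labels within a time point, genotype labels within a feeding, or times within a group, and the real split counts among those as large. Chance is called excluded where fewer than 1 in 20 splits gave as many genes, with no adjustment for the number of results tested in this way. Chance can be excluded for the feeding effect in WT (6378 genes, highest other split 4929, 1 of 100 as large), in ReverbLDKO (332, highest 86, 1 of 100), as the mean of genotypes (3786, highest 550, 1 of 100) and for its difference between genotypes (4695, highest 2926, 1 of 100). It cannot be excluded for the feeding effect in Bmal1LKO (4, highest 6, 2 of 32) and CryDKO (2, highest 98, 28 of 100). For a rhythm that differs between feedings CryDKO met the rule by little (130, highest 126, 1 of 100), and only 2 genes passed with only these groups in the fit. In WT (0, highest 4984, 100 of 100), Bmal1LKO (0, highest 2, 32 of 32) and ReverbLDKO (0, highest 143, 100 of 100) the real count of 0 makes every split as large and the splits decide nothing. The limma fits gave 882, 102 and 280 genes at an unadjusted p under 0.05 in WT, Bmal1LKO and ReverbLDKO. Voom gave none in any of these genotypes, and library weights gave 248 in WT and 912 in ReverbLDKO.

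For genotype against WT chance can be excluded in Bmal1LKO (2721, highest 3953, 4 of 100), CryDKO (6514, highest 3658, 1 of 100) and ReverbLDKO (5758, highest 2591, 1 of 100). It cannot for rhythms that differ from WT, in Bmal1LKO (38, highest 5230, 25 of 100), CryDKO (467, highest 6726, 20 of 100) and ReverbLDKO (107, highest 3783, 10 of 100). Genes rhythmic over the day numbered 2957 in ad libitum WT (highest 4737, 4 of 100) and 1990 in restricted WT (highest 4272, 10 of 100), so that chance can be excluded for the former only. It can be excluded in ad libitum and restricted Bmal1LKO (3, highest 3, 2 of 100; 51, highest 0, 1 of 100), CryDKO (5, highest 4; 720, highest 227; 1 of 100 each) and ReverbLDKO (3, highest 1; 393, highest 10; 1 of 100 each). Splits that call several times the real number, as for rhythms that differ between feedings in WT or from WT, mix libraries of groups whose levels differ. Whether the samples also hold a structure that these labels do not give was not tested.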

How the results depend on the processing

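The tests with other splits, the alternatives planned in advance and the leave-one-out fits were fixed earlier, and the settings named further on as chosen after seeing the data were not. A count of genes is said to move where it changed by more than 1.5 times. Counts that moved numbered 21 of 26 with library weights, 19 of 24 with only the groups compared in the fit, 14 of 26 with no filter on low values, 9 of 26 with every library rescaled to the same sum of FPKM, 4 of 26 with a pseudocount of 0.1 and 3 of 26 with median-of-ratios scaling. Of the alternatives chosen later, 14 of 27 moved after the GC and length correction and 5 of 26 with voom on the recovered reads. For single genes the text names, 6656 alternative values kept their direction and their side of the threshold, 542 kept the direction and were no longer past it, and 29 changed sign. Of the 57 list directions camera called over the 8 contrasts, 2 passed with an estimated correlation. On corrected values these were at 0.0623 for fatty acid synthesis in Bmal1LKO and 0.411 for bile acid genes in CryDKO. The cause of these changes was not tested. A fit of only the groups compared has fewer libraries, yet it raised some counts and lowered others. No filter tests 27875 genes in place of 9958. What depth limits was not tested apart from the number of libraries; with simulated changes, 40% of genes changed by 0.5 log2 were recovered in the ReverbLDKO feeding contrast and 94% of those changed by 1.

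With no filter on low values, feeding counts were 103 in Bmal1LKO, 26 in CryDKO and 534 in ReverbLDKO. No filter gave rhythm differences between feedings for 2 in WT, 117 in Bmal1LKO, 225 in CryDKO and 16 in ReverbLDKO, and from WT for 168 in Bmal1LKO. Rhythmic under no filter, ad libitum and restricted, were 548 and 831 in Bmal1LKO, 61 and 1344 in CryDKO and 33 and 689 in ReverbLDKO. With median-of-ratios scaling, feeding counts were 10 in Bmal1LKO and 4 in CryDKO, and calls shared by WT and ReverbLDKO numbered 111 that rose. With every library rescaled to the same sum of FPKM, feeding counts were 12 in Bmal1LKO, 5 in CryDKO and 1056 in ReverbLDKO, and genotype counts were 4959 in Bmal1LKO, and calls shared by WT and ReverbLDKO numbered 36 that rose and 589 that fell. The same sum of FPKM gave rhythm differences between feedings for 2 in ReverbLDKO, and from WT for 20 in Bmal1LKO. Rhythmic under the same sum of FPKM were 1 in ad libitum Bmal1LKO. With library weights, feeding counts were 938 in Bmal1LKO, 473 in CryDKO, 4136 in ReverbLDKO, 6000 for the mean of 4 genotypes and 7740 for the difference between genotypes, and genotype counts were 4275 in Bmal1LKO, and calls shared by WT and ReverbLDKO numbered 918 that rose and 1768 that fell. Library weights gave rhythm differences between feedings for 248 in WT, 2026 in CryDKO and 912 in ReverbLDKO, and from WT for 1271 in Bmal1LKO, 4751 in CryDKO and 4191 in ReverbLDKO. Rhythmic under library weights were 5365 in ad libitum WT and, ad libitum and restricted, 95 and 616 in Bmal1LKO, 1322 and 2650 in CryDKO and 1000 and 3466 in ReverbLDKO. With only the groups compared in the fit, feeding counts were 32 in Bmal1LKO, 0 in CryDKO and 2381 in ReverbLDKO, and genotype counts were 1677 in Bmal1LKO, and calls shared by WT and ReverbLDKO numbered 380 that rose and 1007 that fell. A fit of only the groups compared gave rhythm differences between feedings for 2 in CryDKO and 66 in ReverbLDKO, and from WT for 16 in Bmal1LKO, 87 in CryDKO and 54 in ReverbLDKO. Rhythmic under a fit of only the groups compared, ad libitum and restricted, were 167 and 61 in WT, 0 and 4 in Bmal1LKO, 0 and 0 in CryDKO and 11 and 668 in ReverbLDKO. With time points as categories, feeding counts were 10 in Bmal1LKO and 0 in CryDKO. With a pseudocount of 0.1, feeding counts were 0 in CryDKO. Rhythmic under a pseudocount of 0.1 were 0 in ad libitum Bmal1LKO, 3 in ad libitum CryDKO and 0 in ad libitum ReverbLDKO. WT replicate 1 alone gave rhythm differences from WT for 69 in Bmal1LKO and 247 in CryDKO. Rhythmic under WT replicate 1 alone were 1505 in ad libitum WT and 406 in restricted WT. WT replicate 2 alone gave rhythm differences from WT for 167 in Bmal1LKO, 809 in CryDKO and 590 in ReverbLDKO. Rhythmic under WT replicate 2 alone were 1555 in ad libitum WT.

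The settings that follow were chosen after seeing the data. After the GC and length correction, feeding counts were 3752 in WT, 14 in Bmal1LKO, 6 in CryDKO, 1570 for the mean of 4 genotypes and 2499 for the difference between genotypes, and calls shared by WT and ReverbLDKO numbered 63 that fell. The GC and length correction gave rhythm differences between feedings for 365 in CryDKO, and from WT for 77 in Bmal1LKO and 772 in CryDKO. Rhythmic under the GC and length correction were 27 in ad libitum Bmal1LKO, 200 in restricted Bmal1LKO, 3 in ad libitum CryDKO, 1422 in restricted CryDKO and 801 in restricted ReverbLDKO. With that correction and only the groups compared in the fit, feeding counts were 2737 in WT, 8 in Bmal1LKO, 0 in CryDKO and 1977 in ReverbLDKO, and calls shared by WT and ReverbLDKO numbered 199 that rose and 226 that fell. The corrected fit of only the groups compared gave rhythm differences between feedings for 1 in CryDKO and 131 in ReverbLDKO. Rhythmic under the corrected fit of only the groups compared, ad libitum and restricted, were 297 and 190 in WT, 0 and 5 in Bmal1LKO, 1 and 0 in CryDKO and 16 and 1122 in ReverbLDKO. With voom on the recovered reads, feeding counts were 2 in Bmal1LKO, and calls shared by WT and ReverbLDKO numbered 115 that rose. Rhythmic under voom were 1 in ad libitum Bmal1LKO, 22 in restricted Bmal1LKO and 3 in ad libitum CryDKO. Without the 3 doubted libraries, feeding counts were 56 in Bmal1LKO and 789 in ReverbLDKO, and calls shared by WT and ReverbLDKO numbered 173 that rose and 314 that fell. The set without the 3 doubted libraries gave rhythm differences from WT for 76 in Bmal1LKO and 301 in CryDKO. Rhythmic under the set without the 3 doubted libraries were 29 in ad libitum Bmal1LKO, 167 in restricted Bmal1LKO and 797 in restricted ReverbLDKO. Without the 8 libraries with pancreas reads, feeding counts were 115 in Bmal1LKO and 1 in CryDKO, and genotype counts were 4357 in Bmal1LKO. The set without pancreas reads gave rhythm differences from WT for 1783 in Bmal1LKO, 2534 in CryDKO and 2093 in ReverbLDKO. Rhythmic under the set without pancreas reads were 4244 in restricted WT, 25 in ad libitum Bmal1LKO, 235 in restricted Bmal1LKO, 0 in ad libitum ReverbLDKO and 695 in restricted ReverbLDKO.

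Signs changed with the GC and length correction, except for Clock in ReverbLDKO, which changed with the restricted groups alone. For Atf5, at -0.96 in the WT feeding contrast, every setting passed on its side of 0, with an adjusted p of at most 0.00633. For the WT feeding contrast, the log2 difference after that correction, with the correction in a fit of WT alone, with the replicate block and with the replicate block of pairs was, in this order, 0.01, 0.01, 0.001 and 0.025 for Dbp and 0.148, 0.148, 0.171 and 0.206 for Pdk2. The same values were 0.03, 0.03, 0.056 and 0.085 for Hmox1 and 0.513, 0.513, 0.524 and 0.549 for Atf5. They were 0.125, 0.125, 0.133 and 0.146 for Tie1 and 0.276, 0.276, 0.273 and 0.284 for Mcm2. Clock was at -0.006 with the pairs and the correction. For the mean of 4 genotypes the corrected difference was 0.066 for Atf5 and 0.068 for Cebpa. Against WT, ReverbLDKO differed by -0.012 for Per1 after the correction, and by -0.003 for Clock with the restricted groups alone.

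The labels give WT libraries of both feedings the same replicate numbers at each time. The deviations of libraries of the same time and number from their group curves correlated at 0.31 to 0.86 in 9 of 11 pairs, at -0.15 in the pair of ZT24 replicate 1 and at 0.01 in that of ZT24 replicate 2. A library correlated best with its own number in 8 of 11 pairs, which is a hint from the data and not part of the design, and the numbers were not taken to pair the libraries. With the replicate number as a block the WT feeding count was 6418, and with a block for each time and number (replicate block, pairs) it was 6748. With the GC and length correction these were 3839 with the replicate block and 4198 with the replicate block of pairs, against 3752 with no block.

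With each library left out in turn, feeding counts were 5995 to 6773 in WT, 1 to 13 in Bmal1LKO, 0 to 28 in CryDKO, 172 to 298 in ReverbLDKO, 3392 to 4543 for the mean of 4 genotypes and 4286 to 5550 for the difference between genotypes. Counts of genes whose rhythm differed between feedings were 0 to 457 in WT, 0 to 0 in Bmal1LKO, 37 to 291 in CryDKO and 0 to 0 in ReverbLDKO. Genotype counts were 2281 to 3351 in Bmal1LKO, 6211 to 6679 in CryDKO and 5293 to 5979 in ReverbLDKO. Counts of genes whose rhythm differed from WT were 21 to 113 in Bmal1LKO, 293 to 1174 in CryDKO and 54 to 884 in ReverbLDKO. Rhythmic genes, ad libitum and restricted, numbered 1561 to 3777 and 951 to 3542 in WT, 0 to 6 and 1 to 41 in Bmal1LKO, 0 to 7 and 302 to 981 in CryDKO, and 0 to 3 and 204 to 299 in ReverbLDKO.

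The feeding count in Bmal1LKO without 1 ad libitum library was 1 (ZT4), 9 (ZT8), 1 (ZT12), 13 (ZT16), 2 (ZT20) and 8 (ZT24). Without 1 restricted library it was 1 (ZT4), 12 (ZT12) and 2 (ZT16). The feeding count in CryDKO without 1 ad libitum library was 1 (ZT6), 0 (ZT9), 1 (ZT12), 0 (ZT15), 1 (ZT21) and 1 (ZT24). Without 1 restricted library it was 24 (ZT6), 0 (ZT9), 4 (ZT12), 0 (ZT15), 1 (ZT18), 28 (ZT21) and 1 (ZT24). The feeding count in ReverbLDKO without 1 ad libitum library was 216 (ZT9), 219 (ZT12), 177 (ZT21) and 193 (ZT24). Without 1 restricted library it was 211 (ZT9), 220 (ZT12) and 172 (ZT24). The count of genes whose rhythm differed between feedings in WT was 1 without ad libitum ZT20 replicate 1, 1 without restricted ZT4 replicate 2 and 457 without restricted ZT16 replicate 1. In CryDKO that count was 82 (ZT6), 80 (ZT12) and 37 (ZT24) without 1 ad libitum library. It was 47 (ZT3), 291 (ZT6), 55 (ZT12) and 196 (ZT21) without 1 restricted library. The count of genes whose rhythm differed from WT in Bmal1LKO was 61 without ad libitum WT ZT16 replicate 2, 113 without restricted WT ZT16 replicate 1 and 21 without restricted Bmal1LKO ZT24. The count of genes whose rhythm differed from WT in CryDKO was 303 without restricted WT ZT12 replicate 2, 1174 without restricted WT ZT16 replicate 1, 311 without ad libitum CryDKO ZT6 and 293 without restricted CryDKO ZT3. Without 1 restricted WT library the count of genes whose rhythm differed from WT in ReverbLDKO was 177 (ZT4 replicate 2), 62 (ZT12 replicate 2), 884 (ZT16 replicate 1), 65 (ZT16 replicate 2) and 67 (ZT24 replicate 1). Without 1 ad libitum ReverbLDKO library it was 70 (ZT12) and 67 (ZT15). Without 1 restricted ReverbLDKO library it was 65 (ZT3), 63 (ZT9), 59 (ZT12), 65 (ZT15), 71 (ZT18), 68 (ZT21) and 54 (ZT24). Rhythmic ad libitum WT genes numbered 1561 without ZT4 replicate 1. Rhythmic restricted WT genes numbered 1176 without ZT4 replicate 1, 951 without ZT12 replicate 2, 3542 without ZT16 replicate 1, 1058 without ZT16 replicate 2 and 1145 without ZT24 replicate 1. Rhythmic ad libitum Bmal1LKO genes numbered 0 without ZT4, 1 without ZT8, 1 without ZT12 and 6 without ZT24. Rhythmic restricted Bmal1LKO genes numbered 18 without ZT4, 8 without ZT8, 29 without ZT12, 10 without ZT16 and 1 without ZT20. Rhythmic ad libitum CryDKO genes numbered 1 without ZT6 and 0 without ZT18. Rhythmic restricted CryDKO genes numbered 314 without ZT3 and 302 without ZT12. Rhythmic ad libitum ReverbLDKO genes numbered 0 without ZT12 and 1 without ZT21. Rhythmic restricted ReverbLDKO genes numbered 206 without ZT6, 204 without ZT9, 232 without ZT12, 250 without ZT15 and 212 without ZT24.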

Other observations

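Npas2 was listed at 0 FPKM in 16 of 16 CryDKO libraries and in 19 of the 67 in all. Hba-a1 was 3.34 ± 0.34 higher in CryDKO than in WT while its paralog Hba-a2 fell by 4.08 ± 0.31 on the log2 scale, and how the counting divided reads that match both genes is not known, so that neither value stands for alpha globin as a whole. Xist stood at 0.01 FPKM at most and Ddx3y at 8.34 at least over the libraries, as in male tissue. Clps exceeded 10 FPKM in 8 libraries: 4 of WT at ZT16, restricted CryDKO at ZT9 and ZT24, and ad libitum ReverbLDKO at ZT3 and ZT9, with highest values of 660.55, 192.41 and 93.12. Heat shock genes were rhythmic in 10 and 8 of 13 cases in WT, ad libitum and restricted, in 8 in restricted CryDKO and 9 in restricted ReverbLDKO, and in limma in none of the 4 other groups.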
